A study of Drosophila melanogaster with 32 samples.

How the data were processed

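Testes of Drosophila melanogaster were profiled in 32 samples: 8 RNA-seq, 20 ATAC-seq and 4 CAGE libraries. Per the labels' protocols, 100 pairs of testes were used per RNA-seq replicate, 300 per CAGE replicate and 10 to 20 per ATAC-seq replicate. Flies of the 48h and 72h groups grew at 22 C for 9 days, were shocked at 37 C for 30 min and were kept at 25 C afterwards. The heat shock control of ATAC-seq was grown, shocked and kept in the same way, for 48 h after the shock. bam mutants grew at 22 C for 12 days, and aly and topi mutants at 25 C for 10 days, without a heat shock. Genotype, temperature, heat shock and time of growth therefore differ together between some groups. The 72h flies were kept longer after the shock than the 48h flies, so age and stage differ together there. RNA-seq libraries were made from rRNA-depleted total RNA.

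Per the submitters' processing notes, the authors used build dm6, Trim Galore 0.4.1, STAR 2.5.1b and 2.5.4b, BWA 0.7.10, deepTools 2.5.4, bedtools 2.25.0 and MACS2 2.1.1, without a statement of which step used which tool. The deposited RNA-seq and CAGE values are raw counts, per gene identifier and per cluster, without normalization; the counting tool, strand setting and annotation are not given in the sources used here. The deposited peak lists give the fold enrichment ratio at the summit and the -log10 q of each peak as the authors called them, 1 list per condition. The deposited nucleosome maps give an occupancy fraction between 0 and 1 and the counts of reads behind each position. How replicates were combined, and which tool called nucleosomes, is not given in the sources used here. Library totals were 20064489 to 28984275 counts for RNA-seq and 19995546 to 25377768 for CAGE. Counting intervals and floors cover counting error only.

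Groups followed the labels: bam, 48h, 72h and aly for RNA-seq and bam and 72h for CAGE, with 2 libraries each. edgeR 4.0.16 in R 4.3.3 was run with filterByExpr by group, TMM scaling and the quasi-likelihood F test on all 8 RNA-seq libraries together, and on the 4 CAGE libraries alone. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, and the number with an absolute log2 fold change of 1 or more was given beside it. Values are normalised counts (edgeR's CPM) with SD. Against a group with 0 counts in all libraries, a fold was given as a lower bound from a floor of 3 counts over the group, for CAGE from the lower library of the other group. With 1 to 3 counts, a ratio with its 95% counting interval was given.

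Of 17559 gene identifiers 17253 had a symbol, and 306, with 3.07% of the counts, had none. Before the data were examined, 19 gene lists were fixed from background knowledge: spermatogonial and early germ cell, tMAC and achi/vis, testis TAFs, early spermatocyte regulators, meiotic division, male meiotic chromosome segregation, spermatid differentiation, Y-linked fertility genes, axonemal dynein, testis proteasome subunits, canonical proteasome subunits, testis mitochondrial paralogs, DNA replication, cytosolic ribosomal proteins, heat shock proteins, somatic cyst and hub cells, testis sheath muscle, accessory gland, and fat body and hemocytes. Some lists share members, so their results are not separate. The genes kl-2, kl-3 and kl-5 are in the Y-linked and axonemal dynein lists. Cyt-c-d is in the spermatid differentiation and testis mitochondrial lists. The axonemal dynein list holds dynein heavy chains and other genes put with them, such as tilB. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation beside it, and member calls were also adjusted over the list alone. The named genes followed a rule fixed at the same time: bam and aly; the 8 largest rises and falls among called genes with a mean of 10 CPM or more in the higher group and no overlap between libraries; the 2 members of each list with the smallest p; and all tMAC and testis TAF genes in aly against 72h. In the text on chromatin, tomboy20 and Ran-like come from that rule and were singled out after their peaks were seen. For CAGE, the 2 largest rises and falls by the same rule were named.

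Genes were called aly-dependent when higher at 72h than in bam and lower in aly than at 72h, each by 2-fold or more. Overlaps were set against the product of the list sizes over the genes tested. Because these comparisons share libraries, 20 data sets without change were simulated, and the correlation and covariance of the changes were set beside the simulated ones. Peaks were called shared at an overlap of 1 bp or more. Planned windows around transcription start sites could not be placed, since the annotation used gives gene ends without strand. Windows of 100 bp either side of both gene ends were used instead, a choice made after seeing the files. Shares were set beside 10000 random gene sets matched in 20 bins of mean expression, and beside 95% Wilson intervals.

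Fixed alternatives were DESeq2 size factors, library size alone, no filter on low counts, DESeq2 1.42.0, limma voom, a replicate block, only the compared groups, each library left out in turn, an adjusted p of 0.01 for the aly sets, a -log10 q of 10 or more, a reciprocal overlap of 50%, equal numbers of top peaks and windows of 500 bp. A test with the spread between CAGE libraries, a test against a 2-fold change and the windows at gene ends were chosen after seeing the data. The replicate block was an alternative only, as fixed beforehand.

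The tests were tried on simulated data with the RNA-seq spread: of changes of 0.5, 1 and 2 on the log2 scale 82.4%, 100% and 100% were recovered, with 15 false calls among 12935 genes. With the spread between CAGE libraries, 2.94%, 57.6% and 100% of these changes were recovered, with 6 false calls among 12968 genes. camera called the 1 raised list and 0 others, and interval overlaps gave 0 mismatches in 2000. The simulation of single genes changed 200 genes, whereas most tested genes were called in the data. These checks therefore do not bear on the scaling, and 1 raised list does not test the preset correlation. The comparison of CAGE with RNA-seq gene by gene, and of CAGE with the aly sets, was not made because clusters carry no gene. Promoter motifs and nucleosomes at start sites were not analysed here, for want of a genome sequence and of strand. A count of nucleosome centres at the summits of gained peaks was made after seeing the data and left out, because the bam map held a position near far fewer of these summits than the 72h map and the difference found was small. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.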

Results

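The series measured testes of Drosophila melanogaster with 3 assays. RNA-seq was made on 8 libraries in 4 groups of 2. The bam group came from bam mutant testes, which are filled with spermatogonia because the germ cells cannot leave proliferation. The 48h and 72h groups came from bam mutants in which a heat shock had switched on Bam, so that the germ cells differentiated together. They were taken 48 h and 72 h after the shock and are labelled as enriched for young and for mature spermatocytes. The aly group came from mutants of aly, a part of the testis meiotic arrest complex (tMAC), which activates spermatocyte genes. CAGE, which counts the 5' ends of transcripts, was made on 2 bam and 2 72h libraries. ATAC-seq, which marks open chromatin, was given as 1 peak list for each of 6 conditions: bam, a heat shock control at 48 h, 48h, 72h, aly and mutants of topi, another tMAC part.

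RNA-seq totals lay between 20064489 and 28984275 counts per library, and CAGE totals between 19995546 and 25377768. Every RNA-seq value below is a mean normalised count (CPM, edgeR's count scaled to library size after TMM) with its SD over 2 libraries per group. The paired RNA-seq libraries differed little beyond counting error: between 6.97% and 7.66% of genes differed between the libraries of a group at the 0.05 level of a chi-square test, against 20.2% and 58.4% of clusters for CAGE. The edgeR spread was 2.11% for RNA-seq and 17.3% for CAGE. RNA-seq p-values therefore measure this narrow spread alone. Counts of list members below are of calls of any size. Where fewer called members of a list changed by 2-fold or more than by less, the counts by 2-fold and those with the spread between CAGE libraries stand beside them. The mitochondrial genome held 11.4% and 11.5% of the counts in the bam libraries, 14.1% and 14.5% at 48h, 18.6% and 19.1% at 72h and 17.7% and 18.1% in aly, so this share differs together with the group. Its rRNA mt:lrRNA alone held 7.33% to 14.2%. On all tested genes, the first principal component held 73.0% of the variance and the second held 21%.

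The genes that were mutated or switched on showed their own levels first. bam (FBgn0000158, chromosome 3R from 25243039 to 25245109, build dm6), the switch from proliferation to differentiation, lay at 96.7 ± 2.57 CPM in bam, 29.4 ± 0.0489 at 48h, 12.9 ± 1.12 at 72h and 96.6 ± 1.12 in aly (SD, n = 2). aly (FBgn0004372, chromosome 3L from 3024129 to 3026521) lay at 38.1 ± 0.615 CPM in bam, 186 ± 3.56 at 48h, 97.2 ± 1.09 at 72h and 70.8 ± 1.64 in aly mutants. Transcripts of both genes were thus counted in their own mutants.

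The first comparison asked what separates young spermatocytes from spermatogonia. At 48h, many transcripts were counted that had 0 counts in bam. tbrd-2, which encodes a testis-specific bromodomain protein, rose from 0 counts in bam to 414 ± 2.0 CPM, at least 6137-fold (floor of 3 counts over the group). cocoon reached 414 ± 3.39 CPM, at least 6136-fold higher, and CG7907 reached 389 ± 0.90, at least 5769-fold higher. sa, a testis-specific TBP-associated factor (TAF), rose from 0 counts to 177 ± 2.03 CPM, at least 2620-fold. The transcript lncRNA:CR43803 and the genes CG18518, CG13455 and CG16854 also rose from 0 counts, by at least 5168-, 2714-, 1831- and 1608-fold. Among the genes that fell most were mtt, which encodes a metabotropic glutamate receptor, 41.3-fold lower at 0.291 ± 0.118 CPM, and the muscle genes Act88F (18.4-fold lower) and fln (9.81-fold lower). Df31, a chromatin decondensation factor, fell from 1242 ± 14.7 to 126 ± 0.38 CPM. CG13690, lncRNA:CR45523, CG14545 and CG4860 fell between 9.90- and 11.9-fold.

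Of the 42 measured spermatid differentiation genes, 42 were higher at 48h than in bam. S-Lap1 and S-Lap7, sperm leucyl aminopeptidases, rose 168-fold to 842 ± 2.77 CPM and 244-fold to 778 ± 4.93 CPM. All 16 testis mitochondrial paralogs and all 14 testis proteasome subunits were higher. ATPsynbetaL, a testis form of an ATP synthase subunit, rose 383-fold, Cyt-c-d, a cytochrome c of the male germ line, 60.4-fold, and the proteasome genes Rpn12R and Rpt6R 142- and 27.4-fold. Of the tMAC and achi/vis genes, 7 of 8 were higher and 1 lower. topi, a zinc finger part of the complex, rose 42.2-fold to 160 ± 1.28 CPM and vis, a homeodomain partner, 18.9-fold. All 5 testis TAFs were higher, can by 320-fold to 175 ± 1.25 CPM. Of 6 early spermatocyte regulators, 5 were higher and 1 lower. fest rose 326-fold and Rbp4, an RNA-binding protein of spermatocytes, 127-fold. Of 11 Y-linked fertility genes, 11 were higher, with ARY at 121-fold and the dynein gene kl-3 at 22.8-fold. Of 11 axonemal dynein genes, 10 were higher and 1 lower, with tilB at 121-fold, counted from 24 reads in bam, and Dhc62B at 9.32-fold.

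The lists of early germ cells and of cell growth and division went down or split. All 22 DNA replication genes were lower, RnrL of ribonucleotide reductase by 5.99-fold and the helicase subunit Mcm7 by 8.01-fold, to 26.4 ± 0.135 CPM. Of 81 cytosolic ribosomal protein genes, 77 were lower, 3 higher and 1 not called; RpS29 fell 2.71-fold and RpS20 2.78-fold. Of 13 spermatogonial and early germ cell genes, 10 were lower, 1 higher and 2 not called. nanos, a translational repressor of early germ cells, fell 7.38-fold to 48.8 ± 0.393 CPM and the piRNA gene AGO3 3.76-fold. Of 11 meiotic division genes, 6 were higher and 5 lower: bol, a translational regulator of meiotic entry, rose 9.02-fold and stg, the mitotic Cdc25, fell 7.53-fold. Of 8 genes of male meiotic chromosome segregation, 3 were higher and 5 lower, with uno at 6.04-fold and SA2 at 6.63-fold higher. Of 30 canonical proteasome subunits, 19 were higher, 7 lower and 4 not called, 0 higher and 2 lower by 2-fold or more and as many with the spread between CAGE libraries; Rpn12 fell 3.04-fold and Rpt3 2.14-fold. For meiotic division 3 were higher and 2 lower by 2-fold or more, and the same numbers with the spread between CAGE libraries.

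Markers of other cell types moved as well. Of 13 somatic cyst and hub cell genes, 9 were lower, 2 higher and 2 not called. Fas3, an adhesion protein of the hub, fell 2.93-fold and Nrt 3.999-fold. Of 14 testis sheath muscle genes, 13 were lower and 1 higher, with Tm1 at 2.28-fold and Mlc2 at 2.66-fold lower. All 14 fat body and hemocyte genes were lower, with Fbp1 at 4.68-fold and Lsp2 at 3.98-fold. Of 11 accessory gland genes, 10 were higher and 1 not called, with Acp36DE at 6.57-fold and Acp95EF at 5.31-fold. Of 15 heat shock protein genes, 12 were lower, 2 higher and 1 not called, although only the 48h group had been shocked. Hsp83 lay 1.89-fold and Hsp70Ab 5.33-fold lower; Hsp70 copies share reads, so the value of each copy is uncertain. Adjusted over the list alone, all of these counts were unchanged except that 3 heat shock genes were higher.

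Over 13495 tested genes, edgeR called 5952 higher and 5640 lower at 48h, of which 4071 and 3067 changed by 2-fold or more. With the spread between CAGE libraries in place of that of the RNA-seq libraries, 4055 and 3047 did. camera, with its preset correlation, called 16 of 19 lists, 9 up and 7 down. The strongest were cytosolic ribosomal proteins (median log2 -1.25, adjusted p = 2.79e-22) and spermatid differentiation (median log2 6.67, adjusted p = 1.45e-19). With an estimated correlation 0 lists were called, and the called lists had adjusted p = 0.107 to 0.205. The 3 lists that camera did not call were meiotic division, male meiotic chromosome segregation and canonical proteasome subunits (adjusted p = 0.78, 0.606 and 0.399; 0.785, 0.66 and 0.66 with an estimated correlation). The median log2 change of all genes was 0.06 with TMM scaling, 0.17 with DESeq2 size factors and 0.25 with library size alone, and it was 0.27 without the first bam library and 0.28 and 0.25 without the first or the other 48h library. Changes near these values thus depend on the scaling and on the libraries in the fit.

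**Figure D1:**
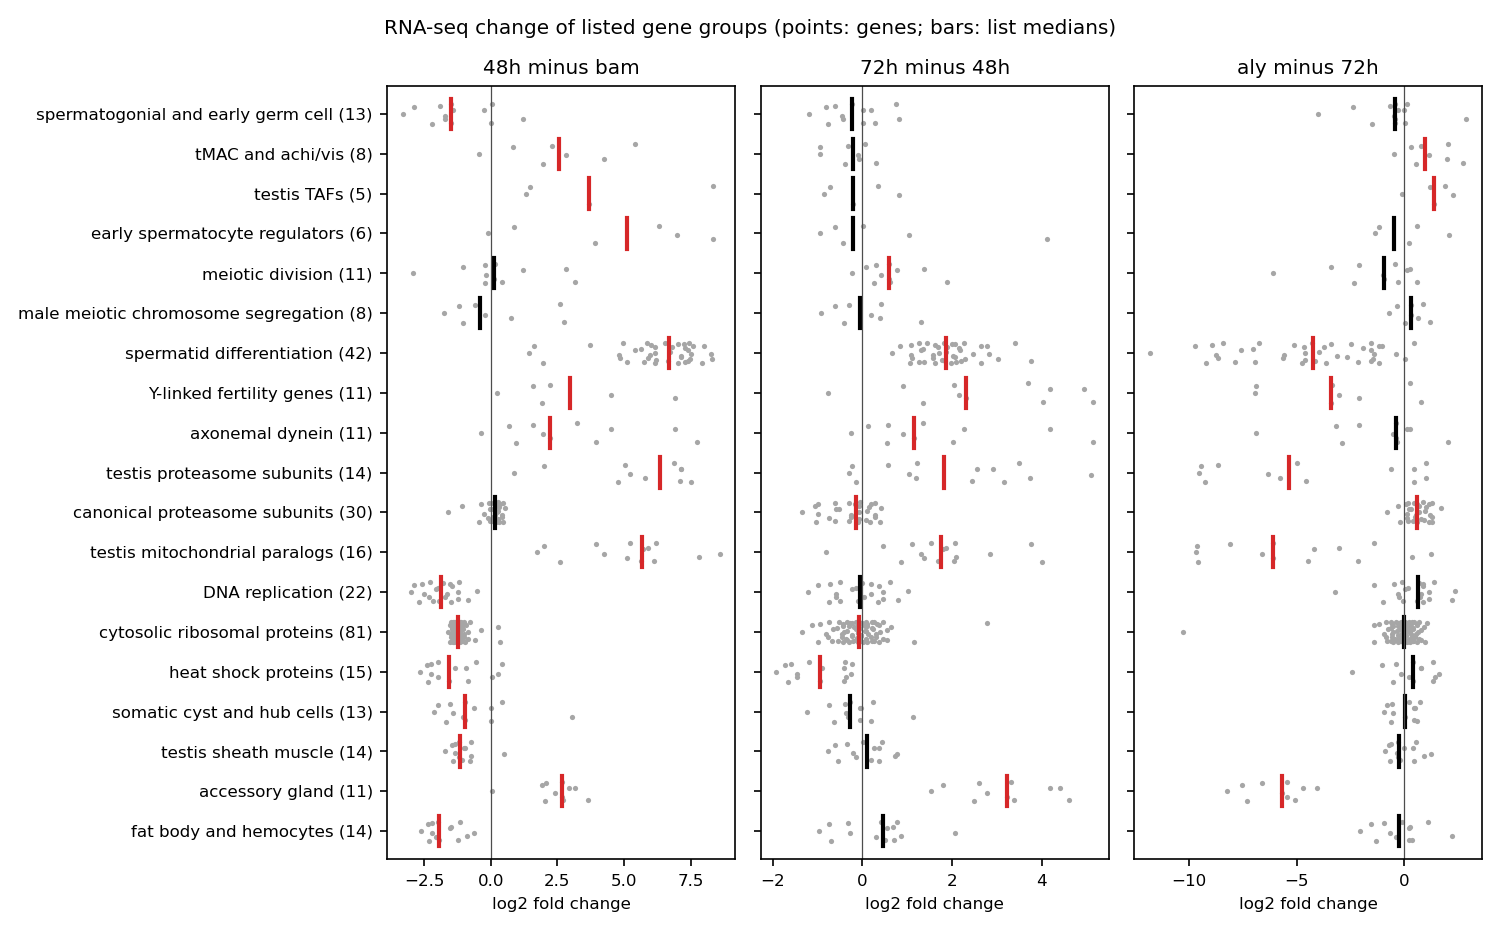
Change of the 19 fixed gene lists in 3 RNA-seq comparisons. The x axes give the log2 fold change, grey points are genes with more than 3 counts in the lower group, bars are list medians (red where camera called the list at its preset correlation), and measured members are in brackets; the spermatid differentiation median lies at 6.67, 1.86 and -4.22 from left to right.

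The second comparison asked what changes as spermatocytes mature from 48h to 72h. The flies were also older at 72h, so age and stage differ together. All 11 accessory gland genes were higher at 72h, Acp95EF by 10.4-fold to 503 ± 2.37 CPM and Acp36DE, a protein of sperm storage, by 2.89-fold to 1317 ± 16.8 CPM. Among the largest rises, Obp56g, an odorant-binding protein gene, rose from 1 count over both 48h libraries to 28.9 ± 0.121 CPM, a ratio of 1762 with a counting interval from 316 to 69650. Acp24A4, Sfp87B, Sfp60F and Sfp24Bb, which encode seminal fluid proteins, rose 258-, 192-, 139- and 128-fold, and EbpII, an ejaculatory bulb protein, 114-fold. Whether these transcripts and those of the accessory gland list came from spermatocytes was not settled. CG10834 and FBgn0039177 rose 230- and 189-fold. The largest falls were of Mal-A1, a maltase (35.9-fold), CG14811 (21.2-fold), CG44329 (16.2-fold) and CG42591 (9.57-fold), followed by mtTFB2, a mitochondrial transcription factor (5.83-fold), the engulfment gene Ced-12 (5.67-fold), the homeobox gene OdsH (5.61-fold) and CG2247 (5.15-fold).

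Of 42 spermatid differentiation genes, 42 rose again. S-Lap1 rose 4.24-fold to 3570 ± 10.7 CPM and Mst84Db, a sperm tail protein gene, 6.89-fold to 1517 ± 16.4 CPM. Of 16 testis mitochondrial paralogs 15 were higher and 1 lower, with COX4L at 2.91-fold and ND-51L2 at 16.1-fold. Of 14 testis proteasome subunits 11 were higher and 3 lower, with Prosalpha4T1 at 13.5-fold and Prosbeta5R2 at 8.99-fold. Of 30 canonical proteasome subunits 19 were lower, 10 higher and 1 not called, with 3 lower and 0 higher by 2-fold or more and 9 lower and 0 higher with the spread between CAGE libraries: Prosalpha4 fell 2.55-fold and Rpn5 2.04-fold. Among 11 Y-linked fertility genes 10 were higher and 1 lower; kl-2 and kl-5, dynein heavy chains, rose 35.3- and 18.2-fold. Of 11 axonemal dynein genes 10 were higher and 1 not called, with Dhc36C at 4.09-fold. Of 11 meiotic division genes 9 were higher, 1 lower and 1 not called, with 2 higher by 2-fold or more and 6 with the spread between CAGE libraries. CycB rose 3.69-fold to 299 ± 4.22 CPM and the kinase gene aurA 2.60-fold.

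Other lists split or went down, most by less than 2-fold. Brackets give the members lower and higher by 2-fold or more, then those lower and higher with the spread between CAGE libraries. Of the tMAC and achi/vis genes 6 of 8 were lower and 2 higher (0 and 0, then 2 and 0), comr by 1.91-fold and aly by 1.92-fold. Of 5 testis TAFs 3 were lower and 2 higher (0 and 0, then 2 and 1), can falling 1.79-fold and mia rising 1.77-fold. Of 6 early spermatocyte regulators 3 were lower, 2 higher and 1 not called (0 and 2, then 2 and 2): Rbp4 fell 1.93-fold and sunz rose 17.3-fold. Of 13 spermatogonial and early germ cell genes 7 were lower, 4 higher and 2 not called (1 and 0, then 4 and 2), with chinmo at 1.75-fold and mei-P26 at 1.70-fold lower. Of 8 genes of male meiotic chromosome segregation 4 were higher and 4 lower (0 and 1, then 2 and 1), with mei-S332 at 2.47-fold higher and SMC1 at 1.52-fold lower. Of 22 DNA replication genes 9 were higher, 9 lower and 4 not called (1 and 1, then 6 and 2), with 10 lower adjusted over the list alone; CycE rose 2.02-fold and geminin fell 2.30-fold. The other list counts of this comparison did not change when adjusted over the list alone. Of 81 cytosolic ribosomal protein genes 45 were lower, 31 higher and 5 not called (2 and 3, then 9 and 5), and the paralog RpL10Aa rose 6.87-fold and RpL38 2.21-fold. Of 15 heat shock protein genes 14 were lower and 1 not called, with Hsp27 at 3.14-fold and Hsp68 at 1.87-fold lower.

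Other cell types were mixed, with brackets as before. Of 13 somatic cyst and hub cell genes 6 were lower, 3 higher and 4 not called (1 and 1, then 3 and 1), with puc at 2.33-fold and Fas3 at 1.67-fold lower. Of 14 testis sheath muscle genes 7 were higher, 6 lower and 1 not called (0 and 0, then 2 and 2), Mlc2 rising 1.71-fold and bt falling 1.52-fold. Of 14 fat body and hemocyte genes 9 were higher, 4 lower and 1 not called (0 and 1, then 3 and 4); the collagen genes Col4a1 and vkg fell 1.95- and 1.63-fold.

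edgeR called 6195 genes higher and 4632 lower, 3890 and 1013 by 2-fold or more. With the spread between CAGE libraries 4652 were higher and 2478 lower, 3866 and 1002 by 2-fold or more. camera called 10 lists at the preset correlation, 7 up and 3 down. These were spermatid differentiation (adjusted p = 6.67e-18), accessory gland (2.84e-06), testis mitochondrial paralogs (7.42e-06), testis proteasome subunits (0.00159), Y-linked fertility genes and axonemal dynein (each 0.00432) and meiotic division (0.0121) upward, and heat shock proteins (3.04e-05), canonical proteasome subunits (0.0103) and cytosolic ribosomal proteins (0.037) downward. With an estimated correlation 0 lists were called, and those 10 had adjusted p = 0.0981 to 0.72. With library size alone, meiotic division lost its call (camera adjusted p = 0.0898). The ribosomal protein list had a median of -0.08 and a mean of 0.02, so its direction is not settled. The split depended on the scaling and on the libraries in the fit. With TMM 57.2% of calls were higher, with library size alone 43.6%, and the median of all genes moved from 0.16 to -0.16. Under TMM it turned as well: 48.5% and 49.1% were higher without the first or the other 48h library, 48.6% with only the compared groups and 49.3% without the filter, with medians of -0.03, -0.02, -0.04 and -0.05. The 2-fold falls numbered 2209 with library size alone, 1671 and 1635 without the first or the other 48h library, and 1621 with only the compared groups in the fit.

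The third comparison set mature spermatocytes against spermatogonia directly. cocoon rose from 0 counts to 1079 ± 10.4 CPM at 72h, at least 16020-fold, and lncRNA:CR43803 and tbrd-2 by at least 9761- and 6939-fold. CG4021, CG7907, CG13455 and CG30393 rose from 0 counts by at least 6381-, 5712-, 4685- and 3666-fold. CG15109 rose from 1 count to 1173 ± 3.38 CPM, a ratio of 52210 with a counting interval from 9369 to 2062000. S-Lap7 rose 1122-fold to 3586 ± 34.0 CPM and S-Lap1 712-fold. Claspin, which acts in the replication checkpoint, fell 10.8-fold to 10.0 ± 0.377 CPM, and the replication regulator E2f1 5.19-fold. mtt, Act88F and lncRNA:CR45523 fell 35.6-, 14.7- and 10.9-fold. Hsp70Ab, Hsp70Ba, Hsp70Aa and Hsp70Bc lay 14.5-, 17.7-, 15.6- and 15.2-fold lower at 72h, with reads shared between the copies.

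All 42 spermatid differentiation genes, 16 of 16 testis mitochondrial paralogs, 14 of 14 testis proteasome subunits, 5 of 5 testis TAFs and 11 of 11 accessory gland genes were higher at 72h than in bam. Higher and lower in turn were 7 and 1 of 8 tMAC and achi/vis genes, 5 and 1 of 6 early spermatocyte regulators, 10 and 1 of 11 Y-linked fertility genes, 10 and 1 of 11 axonemal dynein genes, and 7 and 2 of 11 meiotic division genes, with 2 not called. Male meiotic chromosome segregation split into 3 higher and 5 lower of 8 (median log2 -0.81), and canonical proteasome subunits into 12 higher, 15 lower and 3 not called of 30 (median log2 -0.04). Of the latter 0 were higher and 5 lower by 2-fold or more, and 4 higher and 7 lower with the spread between CAGE libraries. ATPsynbetaL and COX4L rose 220- and 213-fold, Prosbeta5R2 1656-fold and Rpt6R 40.7-fold. topi and vis rose 43.9- and 18.1-fold, can 179-fold, and sa from 0 counts by at least 2283-fold. fest and Rbp4 rose 241- and 65.6-fold, bol and the meiotic Cdc25 twe 13.7- and 3.55-fold, and uno and mei-S332 7.91- and 4.12-fold. ARY and kl-5 rose 227- and 84.6-fold, tilB and Dhc62B 180- and 20.9-fold. Of 22 DNA replication genes 22 were lower, RnrL by 5.87-fold, and of 81 ribosomal protein genes 76 were lower, 4 higher and 1 not called, RpL5 by 3.46-fold. RpL10Aa went the other way, from 1 count to 179 ± 1.74 CPM, a ratio of 7989 with a counting interval from 1434 to 315600. Of 15 heat shock protein genes 14 were lower and 1 higher, Hsp27 falling 5.74-fold. Spermatogonial and early germ cell genes were lower for 10 of 13, with 2 higher and 1 not called. nanos and aub, a piRNA gene, fell 4.39- and 4.58-fold, Prosalpha4 and Rpt3 3.30- and 4.24-fold. Most somatic markers were lower too: 10 of 13 cyst and hub genes, with 2 higher and 1 not called, 12 of 14 muscle genes, with 1 higher and 1 not called, and 13 of 14 fat body and hemocyte genes, with 1 not called. Fas3 fell by 4.88-fold and ci by 3.05-fold, Tm1 and bt each by 2.64-fold, Col4a1 by 4.56-fold and vkg by 3.65-fold. Acp36DE and Acp95EF rose 19.0- and 55.4-fold. Adjusted over the list alone, the counts were unchanged.

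edgeR called 6226 genes higher and 5890 lower, 4946 and 3759 by 2-fold or more. camera called 16 lists, 9 up and 7 down, with spermatid differentiation (median log2 8.29, adjusted p = 7.19e-27) and ribosomal proteins (median log2 -1.33, adjusted p = 1.96e-19) first. With an estimated correlation 0 lists were called and the called ones had adjusted p = 0.141 to 0.152. Meiotic division, male meiotic chromosome segregation and canonical proteasome subunits were not called (camera adjusted p = 0.0851, 0.67 and 0.177). Of the medians, that of the Y-linked fertility genes was 7.83 as fitted and 6.72 with the gene at 0 counts set to its bound. The median change of all genes was 0.06 with TMM, 0.26 with DESeq2 size factors and -0.07 with library size alone, where 48.8% of calls were higher against 51.4% with TMM.

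The fourth comparison asked which transcripts differ between aly mutant testes and testes at 72h. Genotype, heat shock, growth temperature, time of growth and the stages present differ together between these groups. CG7295, expressed at 214 ± 0.794 CPM at 72h, had 0 counts in aly, at least 3151-fold lower. The import receptor paralog tomboy20 (at least 2928-fold lower), CG34241 (at least 2734-fold), CG12035 (at least 2018-fold), CG10909 (at least 1949-fold), the nuclear transport paralog Ran-like (at least 1648-fold), CG43750 (at least 1615-fold) and CG13127 (at least 1566-fold) were also at 0 counts in aly. Mst77F, a sperm chromatin protein, fell 432-fold from 1413 ± 3.99 to 3.24 ± 0.656 CPM and S-Lap7 49.3-fold. CycB, the cyclin of meiotic division, fell 68.0-fold to 4.39 ± 0.185 CPM and bol 10.5-fold.

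Other genes were higher in aly mutants. ppk11, a sodium channel subunit, rose from 0 counts to 15.9 ± 0.252 CPM, at least 217-fold, and ppk16 from 3 counts by a ratio of 355 (counting interval 121 to 1722). Cad88C, a cadherin, rose 245-fold to 427 ± 4.51 CPM and CG17193 138-fold. CG30371, wrapper, sordd2 and CG9289 rose from 1 or 2 counts at 72h, with ratios of 439 (78.5 to 17390), 425 (76.0 to 16840), 423 (75.5 to 16730) and 252 (69.6 to 2090).

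Of the tMAC and achi/vis genes, 7 of 8 were higher in aly and the mutated gene itself was lower, by 1.37-fold. topi rose 6.87-fold from 167 ± 2.12 to 1146 ± 7.73 CPM, comr 4.19-fold, achi 4.08-fold, tomb 2.27-fold, Caf1-55 1.76-fold, vis 1.48-fold and mip40 1.24-fold. With the spread between CAGE libraries, mip40 and aly no longer passed. Of 5 testis TAFs 4 were higher: can 4.92-fold to 479 ± 5.66 CPM, sa 3.73-fold, nht 2.62-fold and mia 2.31-fold. The remaining one, Taf12L, was 1.07-fold lower, 0.13 higher on the log2 scale with library size alone, and not called with the spread between CAGE libraries or without the second library of either group. Of 30 canonical proteasome subunits 27 were higher and 3 lower, Prosalpha6 by 3.35-fold and Prosbeta2 by 2.46-fold higher.

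Spermatid differentiation genes were lower in aly for 40 of 42 members, with 1 higher and 1 not called. Of 16 testis mitochondrial paralogs 14 were lower and 2 higher, COX5BL by 800-fold, from 149 ± 0.940 to 0.184 ± 0.0780 CPM, and COX4L by 8.08-fold. Of 14 testis proteasome subunits 10 were lower and 4 higher, with Prosalpha4T2 at 692-fold and Prosbeta5R2 at 404-fold lower. Of 11 Y-linked fertility genes 9 were lower and 2 higher, kl-2 by 119-fold and ARY by 8.02-fold lower. Of 11 axonemal dynein genes 7 were lower, 3 higher and 1 not called (8 lower adjusted over the list alone), Dhc62B by 7.25-fold. Of 11 meiotic division genes 8 were lower and 3 higher. Of 6 early spermatocyte regulators 3 were higher and 3 lower, Rbp4 rising 4.27-fold and bru1 falling 2.5-fold. Of 8 genes of male meiotic chromosome segregation 5 were higher, 2 lower and 1 not called, with SMC1 at 1.57-fold higher and mei-S332 at 1.62-fold lower. Of 22 DNA replication genes 13 were higher, 6 lower and 3 not called, PolA1 rising 5.16-fold and CycE falling 9.35-fold. Of 81 ribosomal protein genes 36 were higher, 38 lower and 7 not called; RpL10Aa fell 1270-fold and RpL41 2.58-fold. Of 13 spermatogonial and early germ cell genes 9 were lower, 2 higher and 2 not called, nanos falling 5.18-fold and bam rising 7.50-fold.

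Lists of other cells and of stress stood beside these. Of 11 accessory gland genes 11 were lower in aly, Acp95EF by 160-fold to 3.14 ± 0.106 CPM and Acp36DE by 16.3-fold. Of 15 heat shock protein genes 8 were higher, 5 lower and 2 not called, with Hsp27 at 2.54-fold and Hsp23 at 2.55-fold higher. Of 13 cyst and hub genes 6 were lower, 5 higher and 2 not called, with zfh1 at 1.92-fold and eya at 1.51-fold lower. Of 14 muscle genes 8 were lower, 5 higher and 1 not called, sls rising 1.91-fold and Mlc2 falling 1.62-fold. Of 14 fat body and hemocyte genes 6 were higher, 6 lower and 2 not called, vkg falling 4.12-fold and Col4a1 2.89-fold. Many of these list changes in aly were smaller than 2-fold. Higher and lower by 2-fold or more were 1 and 3 of the spermatogonial and early germ cell genes (1 and 4 called with the spread between CAGE libraries), 0 and 4 of meiotic division (1 and 6), 1 and 0 of male meiotic chromosome segregation (3 and 1), 8 and 0 of the canonical proteasome subunits (17 and 1) and 5 and 2 of DNA replication (12 and 3). For ribosomal proteins it was 1 and 5 (12 and 16), for heat shock proteins 4 and 2 (6 and 2), for cyst and hub cells 0 and 1 (2 and 4) and for muscle 1 and 0 (3 and 4).

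edgeR called 5691 genes higher and 6199 lower in aly, 2981 and 4533 by 2-fold or more. camera called 8 lists: tMAC and achi/vis (adjusted p = 0.00277), testis TAFs (0.0041) and canonical proteasome subunits (1.18e-05) upward, and spermatid differentiation (4.27e-20), accessory gland (4.1e-07), testis mitochondrial paralogs (1.2e-06), testis proteasome subunits (0.00924) and Y-linked fertility genes (0.0405) downward. With an estimated correlation 0 lists were called and these had adjusted p = 0.183 to 0.363. With the replicate block, testis proteasome subunits lost their call (camera adjusted p = 0.0749). The median change of all genes was -0.07 with TMM and 0.15 with library size alone, where 54.0% of calls were higher against 47.9% with TMM.

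**Figure D2:**
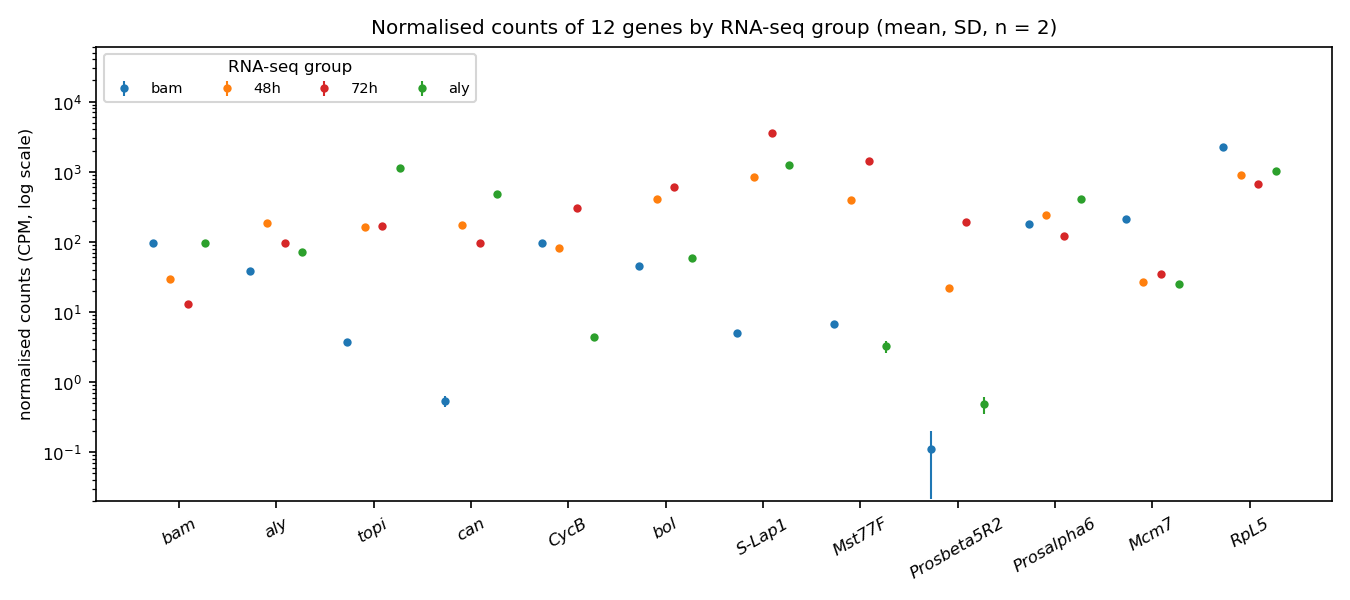
Normalised counts of 12 genes in the 4 RNA-seq groups on a log scale in CPM, as means with SD over 2 libraries (the bars are shorter than the symbols for most genes). topi lay at 3.79 in bam, 160 at 48h, 167 at 72h and 1146 in aly, and Mst77F fell from 1413 at 72h to 3.24 in aly.

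The fifth comparison asked which stage differences are also seen in aly mutants. CG7907 and tbrd-2 rose from 0 counts in bam to 1310 ± 12.5 and 1078 ± 14.3 CPM in aly, at least 19430- and 15990-fold. sa (at least 8517-fold higher), CG12817 (2744), CG10486 (1927), CG18518 (1903), comr (1892) and CG14930 (1693) rose from 0 counts as well, each figure being a lower bound in folds. Of the tMAC and achi/vis genes 8 of 8 were higher, topi by 301-fold, of the testis TAFs 5 of 5, can by 880-fold, and fest and Rbp4 lay 370- and 280-fold higher. Of 42 spermatid differentiation genes 31 were higher than in bam, 5 lower and 6 not called, S-Lap1 rising 249-fold and S-Lap2 205-fold. Of 16 testis mitochondrial paralogs 8 were higher, 4 lower and 4 not called, ATPsynbetaL rising 538-fold. Of 14 testis proteasome subunits 10 were higher and 4 not called, Rpn12R rising 241-fold. Canonical proteasome subunits were higher for 23 of 30, with 6 lower and 1 not called, Rpn7 rising 2.77-fold. Higher and lower in turn were 4 and 1 of 6 early spermatocyte regulators, with 1 not called, 6 and 0 of 11 Y-linked fertility genes, with 5 not called, and 9 and 1 of 11 axonemal dynein genes, with 1 not called. For meiotic division it was 6 and 5 of 11, and for male meiotic chromosome segregation 3 and 5 of 8. By 2-fold or more it was 1 and 2 for meiotic division (3 and 3 with the spread between CAGE libraries) and 5 and 1 for canonical proteasome subunits (14 and 3).

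Lower in aly than in bam were Lsp1gamma, a larval storage protein gene (3 counts left, ratio 1242, counting interval 425 to 6025), and CG30428 (3 counts, ratio 519, 177 to 2521). CG11893, CG33301 and CG13405 fell 371-, 310- and 264-fold, the pigment transporter bw 108-fold and the germ line transcription factor ovo 72.4-fold. On chromosome 3L, from 39947 to 74344, a run of 6 ATAC-seq peaks shared by all other lists was missing from aly. Lsp1gamma (66430 to 68995) lies in this run and CG13405 (73945 to 75332) at its edge. Whether their falls come from the loss of aly or from another difference at this place was not tested. stg, CycB and nanos fell 30.0-, 21.6- and 22.7-fold and CycE 26.3-fold. DNA replication genes were lower for 21 of 22, with 1 higher, and spermatogonial and early germ cell genes for 10 of 13, with 3 not called. Ribosomal protein genes were lower for 76 of 81, with 2 higher (3 adjusted over the list alone) and 3 not called, RpLP1 by 4.81-fold and RpL9 by 3.40-fold. Of 14 fat body and hemocyte genes 12 were lower (13 adjusted over the list alone), 1 higher and 1 not called, vkg falling 15.03-fold. Cyst and hub genes were lower for 10 of 13, with 1 higher and 2 not called, ci by 5.33-fold, muscle genes for 13 of 14, with 1 higher, Tm1 by 3.22-fold, and heat shock protein genes for 13 of 15, with 2 higher, Hsp83 by 2.83-fold. Of 11 accessory gland genes 6 were lower, 1 higher and 4 not called, with 3 lower by 2-fold or more and 5 with the spread between CAGE libraries. edgeR called 5622 genes higher and 5463 lower, 3942 and 3416 by 2-fold or more. camera called 15 of 19 lists, 8 up and 7 down, led by ribosomal proteins (median log2 -1.33, adjusted p = 2.02e-23) and spermatid differentiation (median log2 4.04, adjusted p = 2.78e-08). With an estimated correlation 0 were called and these had adjusted p = 0.154 to 0.217. With the replicate block, early spermatocyte regulators and testis mitochondrial paralogs lost their call (camera adjusted p = 0.0925 and 0.109). Meiotic division, male meiotic chromosome segregation, Y-linked fertility genes and accessory gland were not called at the preset correlation (camera adjusted p = 0.839, 0.955, 0.136 and 0.584). The median change of all genes was 0.01 with TMM and 0.11 with DESeq2 size factors.

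The stage and aly comparisons were then joined. Of 4946 genes higher by 2-fold or more at 72h than in bam, 3560 (72.0%) were lower by 2-fold or more in aly than at 72h and are called aly-dependent here. Another 406 (8.21%) were lower by less, and 980 (19.8%) were not called lower and are called aly-independent; 686 of these were higher in aly. Of the aly-dependent genes 1195 still lay 2-fold or more above bam in aly and 2365 did not. The aly-dependent set held 39 of the 42 spermatid differentiation genes, 14 of 16 testis mitochondrial paralogs, 9 of 14 testis proteasome subunits and 9 of 11 Y-linked fertility genes. It held 0 of the tMAC genes and 0 of the testis TAFs, of which 6 and 4 were aly-independent. It also held 11 of 11 accessory gland genes, whose source in the 72h samples is not known. The set therefore need not hold spermatocyte genes only. Lists that were independent would share 1661 genes. The 72h libraries enter both comparisons, and how much of the overlap comes from them is not known: 20 simulated data sets without change gave a mean of 0.2 genes, but few unchanged genes can reach 2-fold at this spread. The changes in the 2 comparisons had a correlation of -0.748 across genes, against -0.514 in the simulated data, and a covariance of -9.58 against -0.0188. Genes higher at 48h than in bam, a comparison with other libraries, overlapped the genes lower in aly in 2803 of 4071 cases. Independent lists would share 1367 (odds ratio across genes 9.83). Both comparisons still set heat-shocked testes against testes that were not shocked. An effect of the shock would enter both, so this overlap does not single out aly.

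The ATAC-seq comparison asked where chromatin opens. The lists held 30062 peaks for bam, 31173 for the heat shock control, 36412 for 48h, 35547 for 72h, 29559 for aly and 38078 for topi, with 1 list per condition and so no error between replicates. Of the 72h peaks 11447 (32.2%) overlapped no bam peak. Of these, 60.1% were also in 48h, 21.2% in the heat shock control, 30.1% in aly and 35.1% in topi, and 55.2% were in neither mutant. With equal numbers of peaks the order of the mutants turned, to 31.0% in aly and 25.4% in topi. Of the 72h peaks shared with bam, 85.3% were in aly and 91.5% in topi. In the other direction 14.8% of bam peaks were not in 72h and 16.0% were not in the heat shock control. These shares were 4.22% and 7.73% with a stricter q, 31.6% and 26.4% with reciprocal overlap, and 20.0% and 16.6% with equal numbers of peaks, so their order depends on the setting. The gained peaks were weaker, with a median fold enrichment of 2.253 against 3.505 for shared ones.

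Peaks within 100 bp of either annotated gene end were counted per gene, because the annotation at hand gives no strand. Of the 42 spermatid differentiation genes, 5 had such a peak in bam, 5 in the heat shock control, 34 at 48h and 41 at 72h, against 24 in aly and 7 in topi. All 5 testis TAFs had one at 48h, 72h and in aly, but 1 in bam and 1 in topi. can (chromosome 3L, 10263909 to 10267111), sa (3L, 21405425 to 21406738), mia (3R, 5548115 to 5551168) and nht (2L, 15317954 to 15318901) were the 4 that had no peak in bam and topi. aly showed the same order as these 4, while tomboy20 and Ran-like had a peak at 72h and in neither mutant. Testis mitochondrial paralogs went from 4 of 16 in bam to 15 at 72h, 5 in aly and 4 in topi, and testis proteasome subunits from 2 of 14 to 13, 7 and 7. Of 22 DNA replication genes 20 had a peak in bam and 21 at 72h, and of 81 ribosomal protein genes 77 and 79. Of 11 accessory gland genes 1 had a peak in bam and 2 at 72h, of 14 muscle genes 14 and 14, and of 14 fat body and hemocyte genes 5 and 5.

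Of 3524 placed aly-dependent genes, 21.9% (95% Wilson interval 20.5 to 23.2) had a peak at a gene end in bam, 22.6% in the heat shock control, 46.0% at 48h and 63.2% (61.6 to 64.8) at 72h, but 27.4% (25.96 to 28.9) in aly and 25.1% (23.7 to 26.5) in topi. Of 964 aly-independent genes 47.8% had one in bam, 63.7% at 72h and 60.7% in aly. Genes that were lower at 72h stayed between 82.0% and 85.9% in all 6 lists. Over all 13219 placed genes the share was 60.2% in bam, 61.4% in the heat shock control, 71.2% at 48h and 75.4% at 72h. In aly and topi it was 63.7% and 62.6%. Peak strength differed between lists as well, with a median -log10 q of 15.1 in bam, 23.1 at 72h and 17.5 in aly. The shares were not adjusted for this difference. Random sets matched to the aly-dependent genes on mean expression had a median of 46.6% in bam, 65.3% at 72h and 49.5% in aly. The match used the same mean per gene for all lists, not the expression in each condition. The aly-dependent genes are by definition lower in bam and in aly than at 72h. The medians for bam and aly therefore do not control for expression there. Among genes with a peak at 72h and none in bam, 242 of 1482 aly-dependent genes (16.3%) had a peak in aly, against 119 of 180 aly-independent ones (66.1%, Fisher's exact test across genes, two-sided p = 4.85e-43). In topi the shares were 9.04% and 33.3% (Fisher's exact p = 9.26e-17). The heat shock control showed the same order, 66 (4.45%) against 36 (20.0%), as did 48h with 55.5% against 78.3%. The control list held 84.0% of the bam peaks, and these genes were chosen for having no peak in bam. Its low shares were thus partly set by that choice. How much of the contrast in aly and topi comes from the mutations cannot be told from these values. Genes are not independent replicates, and the window moved the shares of the aly-dependent genes. With 500 bp they were 37.4% in bam, 72.9% at 72h, 41.2% in aly and 45.6% in topi, so the order of aly and topi turned.

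**Figure D3:**
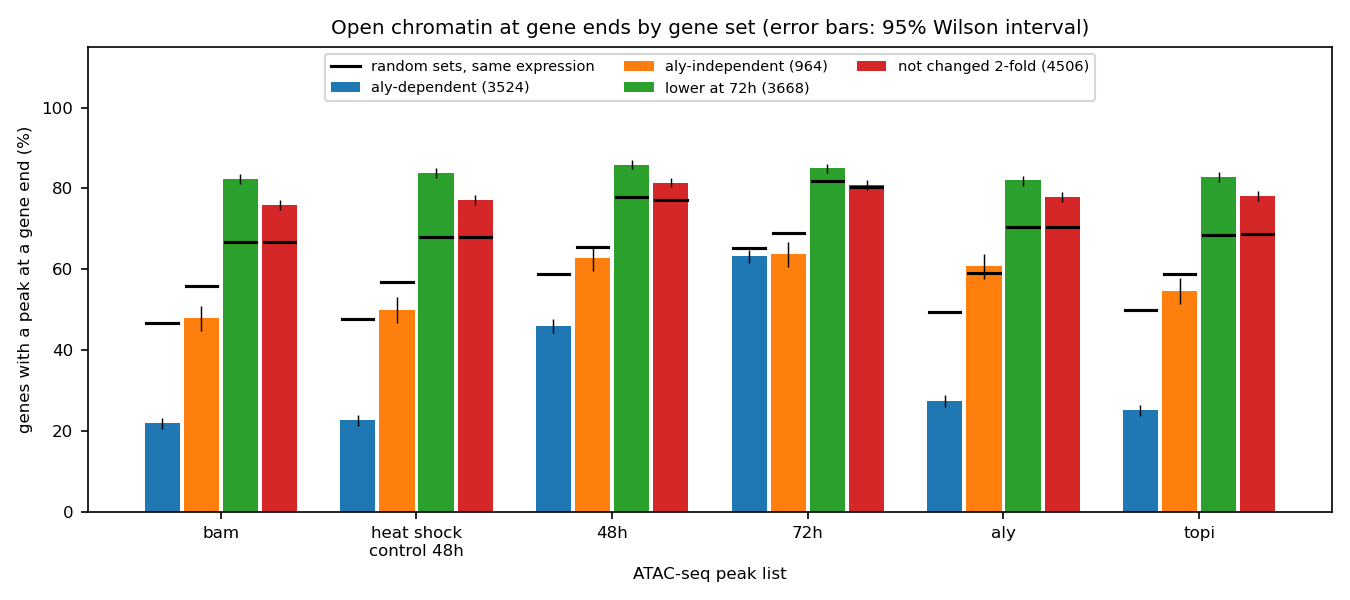
Percent of genes with an ATAC-seq peak within 100 bp of a gene end, for 4 gene sets (number of genes in brackets) in 6 peak lists. Bars start at 0, error bars are 95% Wilson intervals, and black lines are medians of 10000 random sets matched on mean expression. The match used the same mean per gene for all lists, not the expression in each condition. The aly-dependent genes lie at 63.2% at 72h, 27.4% in aly and 25.1% in topi.

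The nucleosome maps, also 1 per condition, held 109509 positions in bam, 116245 at 72h, 99570 in aly and 139279 in topi, with median occupancies of 0.847, 0.852, 0.850 and 0.838. Median reads per position differed between maps (7 in bam, 13 at 48h, 10 at 72h), so the numbers were not compared.

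CAGE asked the stage question through 5' ends. Its clusters carry neither gene nor position, so no gene can be named. Of 16971 tested clusters, edgeR called 8325 higher and 5018 lower at 72h than in bam, 7531 and 2549 by 2-fold or more. The 2-fold falls numbered 1078 with DESeq2 size factors, 6486 with library size alone, 933 in DESeq2 and 750 when tested against a 2-fold change. A group of 3020 clusters had 0 counts in both bam libraries, and 3018 of them were called higher; 2 clusters had 0 counts in both 72h libraries. Every cluster had 90 or more counts over the 4 libraries, so a cluster at 0 in bam had 90 or more at 72h and its call was nearly fixed. Under 10 counts were found for 5320 clusters in bam and for 42 at 72h, and how the clusters were chosen is not given in the sources used here. cluster7364 rose from 0 counts to 569 ± 358 CPM (315 and 822 in the 2 libraries), at least 6164-fold in the lower library, and cluster15508 to 428 ± 61.5 CPM, at least 7507-fold in the lower library. cluster6619 fell from 10.6 ± 0.157 CPM to 2 counts, a ratio of 190.2 with a counting interval from 52.4 to 1574, and cluster3448 fell 34.6-fold from 14.6 ± 1.32 CPM. The share of 2-fold changes that were rises grew from 65.6% in the least abundant of 4 equal groups of clusters to 87.2% in the most abundant. The split of calls depended on scaling, with 62.4% higher under TMM, 75.4% under DESeq2 size factors, 78.5% in DESeq2 and 48.0% with library size alone, and the median change was 0.44, 0.76, 0.76 and -0.26. Without the first bam library 3131 clusters were called lower, and without the second 72h library 1534 were lower by 2-fold or more.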

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

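The test with the spread between CAGE libraries, the test against a 2-fold change and the windows at gene ends were chosen after the results were seen. The cause of the differences was not tested except where the setting shows it. Between 72h and 48h, the 2-fold falls (1013) numbered 2209 with library size only, 1770 with no filter, 1621 with only the 2 groups compared and 1034 to 1671 when leaving out 1 library; all falls (4632) numbered 2478 with the spread between CAGE libraries, which is wider by construction. For CAGE, the 2-fold falls (2549) numbered 1078 with DESeq2 size factors, 6486 with library size only, 933 with DESeq2, 750 when tested against a 2-fold change and 1534 to 3063 when leaving out 1 library; all falls (5018) numbered 2865, 7880 and 2411 with the first 3 of these, and 3131 to 5855 when leaving out 1 library. Of 292 counts of calls under alternatives, 277 stayed within 1.5 times. Of 3627 values of named genes under alternatives, 1 changed direction: Taf12L in aly against 72h, to 0.13 with library size only; 35 kept their direction and lost their call, 30 of these when tested against a 2-fold change. Of 72h peaks, the percent not in bam (32.2) was 36.0 with a stricter q, 42.2 with reciprocal overlap and 25.3 with equal numbers; of bam peaks, the percent not in 72h (14.8) was 4.22, 31.6 and 20.0, and not in the heat shock control (16.0) 7.73, 26.4 and 16.6; of gained peaks, the percent in aly (30.1) was 28.2, 28.2 and 31.0, and in topi (35.1) 37.2, 31.1 and 25.4. The percent of aly-dependent genes with a peak at a gene end was, with a stricter q and with 500 bp, 17.9 and 37.4 in bam, 57.9 and 72.9 at 72h (60.7 with equal numbers), 22.2 and 41.2 in aly, and 20.9 and 45.6 in topi (22.7 with equal numbers). Of 95 list results 65 were called, and all 65 lost their call with an estimated correlation. With the replicate block 3 lost it and with library size only 1, where 2 others gained one. Library differences correlated across groups by 0.0298 to 0.0961 over genes, under the limit of 0.1 set for pairing, although 42 of 9376 genes differed between libraries 1 and 2 in the same direction in all 4 groups, so for some genes the number marks something shared. With the replicate block the calls in 72h against 48h were 6179 higher and 4644 lower, against 6195 and 4632, and the camera adjusted p was 0.0749 for testis proteasome subunits in aly against 72h, 0.0925 for early spermatocyte regulators and 0.109 for testis mitochondrial paralogs in aly against bam. The aly-dependent genes numbered 2929 to 3855 over all settings, of which 2915 and 3557 were among the 3560. Not run were the interaction of RNA-seq with CAGE, the overlap of CAGE with the aly sets, the most upstream start site and the nucleosome windows, for want of genes, positions and strand. With 2 libraries a group, the spread between animals is known only as far as these libraries show it.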

Other observations

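The tests on replicate libraries, of accessory gland tissue and of X-linked genes at 10 CPM or more in bam were chosen after the results were seen, as was the interval on accessory gland peaks. The tests of accessory gland chromatin and the other tests of the X were written beforehand, although the medians of the X were known by then.

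Genes lay unevenly over the chromosomes in 72h against bam. The 28 tested Y genes had a median log2 change of 6.79, and 26 of them were higher by 2-fold or more; camera gave adjusted p = 0.0172 at the preset correlation and 0.28 with an estimated correlation. The 95 genes of chromosome 4 had a median of -0.67 (camera adjusted p = 0.00532, and 0.066 with an estimated correlation). The X did not pass (adjusted p = 0.165 and 0.192). Of genes 2-fold lower at 48h than in bam, 637 of 3067 were 2-fold higher in aly than at 72h, against 678 if the lists were independent.

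Libraries of an RNA-seq group agreed closely. At most 7.66% of genes differed between the libraries of a group at the 0.05 level of a chi-square test, so 1 RNA preparation sequenced in both libraries could account for it, and so might pools of 100 testis pairs that hardly differ; the design cannot tell these apart. The total of library 2 was 1.11 to 1.12 times that of library 1 in all 4 RNA-seq groups, against 0.938 and 1.27 times in the CAGE groups. Such an even ratio could arise with 1 preparation or with separate pools, so it does not part them. It was seen after the results. Between libraries 1 and 2, 42 of 9376 genes differed in the same direction in all 4 groups where chance gives 0.00733. Among them 7SLRNA:CR42652 was 1.69 to 1.78 times higher in library 2 at equal depth and mt:lrRNA 1.02 to 1.04 times. No biological explanation was tested.

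Accessory gland genes were higher at 72h. That 11 of 11 listed genes were 2-fold higher at 72h than at 48h restates the pattern, so accessory gland tissue or its RNA in the 72h samples stays open without a test that could decide it. For accessory gland genes switched on in spermatocytes with their chromatin opened, 2 of 11 genes had a 72h peak at a gene end (18.2%, 95% Wilson interval 5.14 to 47.7). This meets the bound of at most 2 genes that was written beforehand against this explanation, but not by more than its spread: the interval, added after the value was seen, also holds the 45% that the explanation asks for, so it stays open. The count takes any 72h peak, and 1 of the 11 genes had a peak in bam already, so not every counted peak need be newly opened. Both explanations may hold in part, and the fall of all 11 genes in aly against 72h does not part them.

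X-linked genes lay lower at 72h than in bam, with a median log2 change of -0.42 against 0.18 for autosomes (permutation p = 5e-04, the smallest that 2000 resamples give, with genes not independent). For a shift of the whole X chromosome, ribosomal protein and proteasome genes on the X lay -0.26 from those on the autosomes (17 against 93 genes, permutation p = 0.207), which leaves it open. That few genes switched on in spermatocytes lie on the X could also contribute, but 11.1% of X-linked genes went from below 1 CPM to 10 CPM or more against 12.0% of autosomal genes (Fisher's exact p = 0.221). It does not account for genes already at 10 CPM or more in bam, whose median on the X lay -0.29 from that on the autosomes (medians -0.99 and -0.70, 1157 against 5497 genes, permutation p = 5e-04). For the other genes it stays open, and a shift of the whole X stays open for all. By 2-fold or more, 28.5% of X-linked genes were higher and 35.9% lower. On 2L, 2R, 3L and 3R 36.4% to 43.4% were higher and 23.3% to 27.3% lower. On chromosome 4 it was 17.9% and 35.8%. A shift of the whole X would also lower the share of rises, so these shares do not part the explanations.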
